A study of Mus musculus with 12 samples.

How the data were processed

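Messenger RNA levels were measured by RNA sequencing in L929, an established mouse fibroblast line, in 12 samples that the labels place in 4 groups of 3. The groups were mock, HT-DNA, HT-DNA with AOA, and HT-DNA with AOA and Asp. Per the labels, wild-type cells in 6-well plates received HT-DNA, a transfected DNA, with Lipofectamine 2000 for 6 h. The dose is given as 0.5, with a unit whose order is garbled and which was read here as µg per ml. AOA was given at 0.5 mM from 1 h before the DNA, and Asp at 20 mM. In this field AOA is the usual short form of aminooxyacetate, an inhibitor of aminotransferases, and Asp that of aspartate. The labels do not spell either out, and do not say whether mock cells received the transfection reagent. Nothing states that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The groups with AOA all received HT-DNA. No group with AOA or Asp alone, or with HT-DNA and Asp but no AOA, was analysed here.

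Total RNA was extracted with TRIzol and sequenced by Majorbio, per the labels' protocols. The deposited table holds estimated counts per gene, which need not be whole numbers: 14.4% to 16.6% of the values of a library were not whole. The aligner, the counting program, the strand setting and the genome build are not given in the sources used here, so no coordinates are printed. The table held 56287 entries, 55414 of them with an Ensembl gene identifier and 873 with an identifier of an assembled locus. The assembled loci took 0.494% to 0.634% of the counts of a library. No count was present in any library for 26710 entries. The means per group that the authors placed beside the library columns equalled the means of those columns within 3.3e-05 and were not used further.

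Estimated counts were rounded to whole numbers. Rounding changed a value by at most 0.5. Library totals lay between 19944571 and 27309291 estimated counts. In the pairs of replicates, the chi-square per degree of freedom over genes with 20 or more counts in the pair was 2.15 to 7.96, so the replicates differed by more than sampling noise and were kept as distinct libraries. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 14694 genes. Libraries were scaled with TMM factors, and CPM were computed on the scaled library sizes. All 12 libraries entered a single fit with a term per group, which left 8 residual degrees of freedom. Each of the 4 comparisons was tested with edgeR's robust quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were obtained from the fold change and its F statistic. The common biological coefficient of variation was 0.0534.

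Before the data were examined, 26 gene lists, the tests and the rule for naming genes were fixed. A list was tested when at least 3 members were measured, which held for 25 lists. Lists were tested with camera of limma 3.58.1 on log CPM (prior count 2) with a preset correlation between genes of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. fry was run beside them. camera compares a list with all other genes, while fry asks whether the members move, on balance, in a single direction. GO and KEGG terms that the deposited table pairs with genes were tested with a one-sided Fisher's exact test for terms of 5 to 500 tested genes, against all tested genes with any term of that source. Adjustment was over the terms of a comparison and direction.

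Genes were named by rule among those with an adjusted p under 0.05, a mean of 5 CPM or more in the higher group, no overlap of the 2 groups' CPM and a symbol that is not a clone or number name. The rule took the 6 largest rises, the 6 largest falls and up to 3 members of each list with the largest absolute change. In addition, Ifnb1, Isg15, Ifit1, Cxcl10, Ccl5, Cgas, Sting1, Got1, Got2 and Asns were named in every comparison whatever their values. Genes of the Ifit, Oas, H2 and Apol9 families share sequence with close copies, and mitochondrial transcripts with nuclear copies. Estimated counting can move reads between such copies, and between overlapping or antisense genes, so their values are uncertain.

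Comparisons that share libraries have correlated errors. For these, 10 simulated data sets with no effect were drawn from the fitted dispersions and the real library sizes. Covariances were also recomputed with no library in both fold changes. The fit was tested on simulated data with 200 changed genes per comparison. At a fold of 1.5, the fit of 14694 genes recovered 87.5% of the changed genes for HT-DNA against mock, 68.1% for AOA, 70% for Asp and 59.6% for AOA with Asp against HT-DNA. At a fold of 2 the shares were 79.6%, 83.7%, 87.8% and 78%, and 0.0700% to 0.112% of unchanged genes were called. Intervals and floors given for low counts cover counting error only, since reads without molecular identifiers are not independent molecules.

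The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library size alone, no filter, a filter of 1 CPM in 3 samples, a fit of only the 2 groups compared, a replicate block, glmTreat against a fold of 1.5, and leaving out each library in turn. Removal of length and GC trends (natural splines with 4 degrees of freedom, GENCODE M21 annotation) and removal of the 10 most counted genes were added after the data were seen. Scripts ran under Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.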

Results

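RNA of 12 libraries of the mouse fibroblast line L929 was compared in 4 groups of 3. The groups were mock, transfected HT-DNA for 6 h, HT-DNA with AOA, and HT-DNA with AOA and Asp. The mock libraries held 21484229 to 25102309 estimated counts and the HT-DNA libraries 19944571 to 26404043. The HT-DNA+AOA libraries held 20876925 to 27309291 and the HT-DNA+AOA+Asp libraries 20466001 to 24380878. Values per group are mean CPM ± SD over n = 3 libraries, and 14694 genes were tested. The first principal component held 45.9% of the variance. It placed the HT-DNA+AOA libraries at 49.6 to 55.8, apart from mock at -34.3 to -32.7, HT-DNA at -8.14 to -6.58 and HT-DNA+AOA+Asp at -13.4 to -12.5. On the second component, with 14.4%, mock lay at 24.3 to 25.9 and HT-DNA at -21.1 to -17.7.

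**Figure D1:**
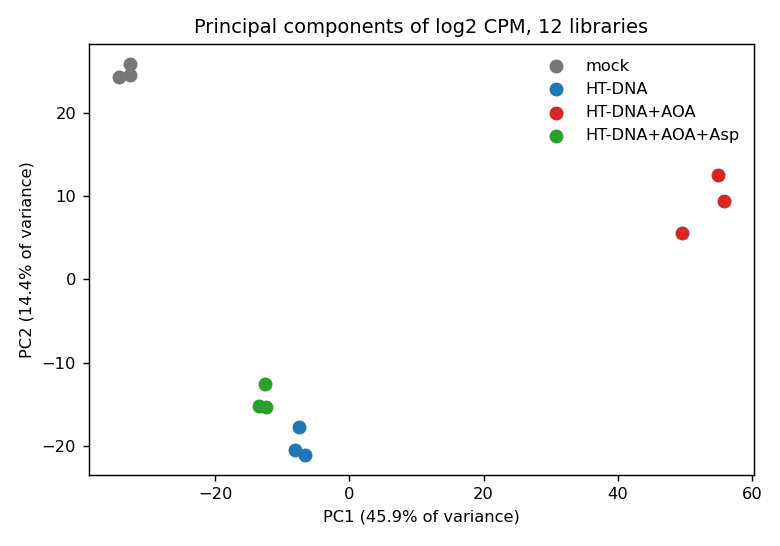
Positions of the 12 libraries on the first and second principal components of log2 CPM, with a point per library coloured by group and axes in component units. The HT-DNA+AOA libraries lie at 49.6 to 55.8 on the first component, and all other libraries lie below 0.

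HT-DNA was compared with mock to ask how the cells responded to transfected DNA. Whether mock cells received the transfection reagent is not stated, so changes called here may include effects of the reagent. The chemokines Cxcl10 and Ccl5 rose from low counts in mock, and 45 of 75 measured interferon-stimulated genes rose. Cxcl10, a chemokine of the interferon response, rose from 0.154 ± 0.0236 to 35.6 ± 1.33 CPM (log2 fold change 7.80, SE 0.19, edgeR adjusted p = 6.77e-17). Ifit1, an antiviral RNA-binding protein, rose from 0.392 ± 0.128 to 65.0 ± 3.98 CPM (log2 fold change 7.35, SE 0.14, edgeR adjusted p = 1.46e-19). Isg15, a ubiquitin-like modifier, rose from 1.94 ± 0.387 to 38.3 ± 3.23 CPM (log2 fold change 4.29, SE 0.11, edgeR adjusted p = 7.07e-18). Ccl5, another chemokine, had 2 counts in the mock group and 1789 in the HT-DNA group, a ratio of 846 (95% counting interval 234 to 6991).

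By edgeR's test, 3112 genes were higher and 2911 lower under HT-DNA, of which 171 and 234 changed at least 2-fold. With library size alone as scaling, the split was 2417 higher and 3740 lower. Of the 25 lists tested, 9 passed camera with the preset correlation and 2 with an estimated correlation. Here and below, counts adjusted over the list alone are given where they differed from those adjusted over all genes. Among the 75 measured interferon-stimulated genes, 45 rose, 4 fell and 26 did not pass, or 50 and 5 adjusted over the list alone, with a median log2 fold change of 0.57 (camera adjusted p = 5.70e-13, or adjusted p = 0.0425 with an estimated correlation). The members that fell, named after their values were seen, were Ifi203, Ifi27, Mov10 and Nlrc5, with log2 fold changes of -0.23, -0.38, -0.33 and -0.22. The other large rises by the naming rule were Rsad2, the antiviral enzyme viperin, at 6.24 (SE 0.23), Oasl1 at 5.59 (SE 0.068) and Hdc, which makes histamine, at 4.95 (SE 0.28). The edgeR adjusted p of these was 8.22e-14, 1.03e-23 and 1.72e-11. None of the 9 type I interferons and ligands of the list passed the expression filter. Ifnb1, which encodes interferon beta, had 0 counts in all 6 libraries of this comparison, where a floor of 3 counts per library corresponds to 0.114 to 0.150 CPM.

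Genes of nucleotide synthesis rose as a group: of 26 measured, 22 rose, 2 fell and 2 did not pass, or 23 and 2 adjusted over the list alone (camera adjusted p = 9.30e-09, or adjusted p = 0.0493 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 263 ± 5.38 to 488 ± 7.60 CPM (log2 fold change 0.89, SE 0.044, edgeR adjusted p = 1.37e-12). Ctps, the CTP synthase, had a log2 fold change of 0.60 (SE 0.043) with edgeR adjusted p = 5.95e-10. Of 32 glycolysis and HIF targets, 21 rose, 4 fell and 7 did not pass (camera adjusted p = 0.000129, or adjusted p = 0.155 with an estimated correlation). Hk2, a hexokinase, was at 0.74 (SE 0.045) with edgeR adjusted p = 3.71e-11. For the 24 G2 and M phase genes, 17 rose, 1 fell and 6 did not pass, or 18 and 1 adjusted over the list alone (camera adjusted p = 0.000368, or adjusted p = 0.155 with an estimated correlation). For the 22 S phase genes, 12 rose, 2 fell and 8 did not pass (camera adjusted p = 0.00553, or adjusted p = 0.219 with an estimated correlation). Heat shock genes numbered 14, of which 10 rose, 2 fell and 2 did not pass (camera adjusted p = 0.00275, or adjusted p = 0.155 with an estimated correlation). Hspa8, a constitutive chaperone, rose from 1476 ± 38.0 to 2652 ± 133 CPM. Of 20 endoplasmic reticulum stress genes, 11 rose, 2 fell and 7 did not pass, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0105, or adjusted p = 0.474 with an estimated correlation). Of 34 genes of the TCA cycle and respiratory chain, 10 rose, 1 fell and 23 did not pass (camera adjusted p = 0.0472, or adjusted p = 0.706 with an estimated correlation). That camera call was lost with library size alone as scaling, with a filter of 1 CPM, with only the 2 groups compared and with a replicate block. It was also lost with length and GC trends removed, and without mock replicate 1 or 2 or HT-DNA replicate 1 or 2 (adjusted p = 0.0567 to 0.713 over all alternatives that ended it).

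Of 28 NF-kB and inflammatory targets, 12 rose, 2 fell and 14 did not pass, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.0105, or adjusted p = 0.570 with an estimated correlation). The members that fell, named after their values were seen, were Tnfaip2 and Traf1, at -0.17 and -0.60. Ccl7 and Ccl2, monocyte chemokines, had log2 fold changes of 0.80 (SE 0.059) and 0.69 (SE 0.056), and Relb, an NF-kB subunit, 0.78 (SE 0.088). The edgeR adjusted p of the 3 genes was 2.60e-09, 5.04e-09 and 2.89e-07. Of 20 components of cGAS-STING and cytosolic nucleic acid sensing, 6 rose, 5 fell and 9 did not pass, with camera adjusted p = 0.756. That list as fixed also holds Ifnar1, Ifnar2, Tyk2 and Jak1, of interferon receptor signalling. The KEGG Cytosolic DNA-sensing pathway was enriched among higher genes (23 of 44 genes against 12.1 expected, adjusted p = 0.0210, one-sided Fisher's exact test). KEGG RNA polymerase was enriched by the same test (18 of 28 genes against 7.68 expected, adjusted p = 0.00322). Genes shared by both terms were not counted, so which members carried the DNA-sensing term is not known. Trex1, a cytosolic DNA exonuclease, rose from 2.74 ± 0.359 to 5.88 ± 0.889 CPM (log2 fold change 1.11, SE 0.15, edgeR adjusted p = 2.69e-06). Sting1, the adaptor downstream of cGAS, fell from 8.23 ± 0.762 to 5.75 ± 0.345 CPM (log2 fold change -0.52, SE 0.11, edgeR adjusted p = 0.000856). Cgas, the DNA sensor, was at 0.20 (SE 0.13) with edgeR adjusted p = 0.269.

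Other genes were lower under HT-DNA. Slc6a9, a glycine transporter, fell from 140.0 ± 4.14 to 51.1 ± 2.81 CPM (log2 fold change -1.46, SE 0.047, edgeR adjusted p = 6.01e-16). Slc5a3, the inositol transporter induced by NFAT5, fell from 144 ± 5.96 to 66.9 ± 3.06 CPM (log2 fold change -1.11, SE 0.074, edgeR adjusted p = 6.76e-09), and of the 14 osmotic stress genes 2 rose, 7 fell and 5 did not pass, with camera adjusted p = 0.188. Lpin1, a phosphatidate phosphatase, had a log2 fold change of -1.87 (SE 0.10), Mturn -2.71 (SE 0.28), Slco4a1 -2.11 (SE 0.16) and Tcim -2.07 (SE 0.21), with edgeR adjusted p of 1.72e-11, 1.20e-06, 1.32e-09 and 5.90e-08. Pagr1a fell further, at -4.05 (edgeR adjusted p = 0.0279), but its call was lost under 8 alternatives, glmTreat not counted. Of 28 cholesterol and fatty acid genes, 4 rose, 12 fell and 12 did not pass, or 4 and 13 adjusted over the list alone, with camera adjusted p = 0.0665. Of 21 p53 targets, 4 rose, 5 fell and 12 did not pass, with camera adjusted p = 0.895. Among KEGG terms, genes higher under HT-DNA were enriched for Spliceosome (84 of 129 genes against 35.4 expected, adjusted p = 2.72e-17) and Ribosome biogenesis in eukaryotes (55 of 69 genes against 18.9 expected, adjusted p = 2.72e-17), by one-sided Fisher's exact tests. Genes that were lower were enriched for Lysosome (55 of 111 genes against 23.6 expected, adjusted p = 7.47e-09).

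Among the genes named in every comparison, Got1, the cytosolic aspartate aminotransferase, was at 0.08 (SE 0.045) and Asns, the asparagine synthetase, at 0.05 (SE 0.042), with edgeR adjusted p of 0.160 and 0.356. Got2, the mitochondrial aspartate aminotransferase, was at 0.14 (SE 0.042) with edgeR adjusted p = 0.0117, a call that was lost with library size alone as scaling (adjusted p = 0.131), without mock replicate 1 (0.0605) and without HT-DNA replicate 1 (0.0770). Markers of other cell types were few, with 3 macrophage and leukocyte genes and 3 endothelial genes measured. Cd68, a macrophage marker that fibroblast lines also express, was at 295 ± 11.9 CPM in mock and 249 ± 3.50 CPM under HT-DNA (log2 fold change -0.25, SE 0.047, edgeR adjusted p = 0.000160). Vwf, an endothelial gene, was at 5.45 ± 0.777 and 2.44 ± 0.186 CPM (log2 fold change -1.16, SE 0.16, edgeR adjusted p = 3.79e-06).

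HT-DNA with AOA was compared with HT-DNA to ask what AOA changed in cells that had received HT-DNA. Since no group here had AOA without HT-DNA, an effect on the response to DNA cannot be told apart from an effect of AOA whatever the DNA. Most interferon-stimulated genes and NF-kB targets rose, and most genes of mitosis, sterol synthesis and endoplasmic reticulum stress fell. Cxcl10 rose from 35.6 ± 1.33 to 181 ± 22.99 CPM (log2 fold change 2.35, SE 0.071, edgeR adjusted p = 2.76e-15). Ifit1 rose from 65.0 ± 3.98 to 137 ± 6.98 CPM (log2 fold change 1.08, SE 0.063, edgeR adjusted p = 1.04e-11). Cxcl2, a neutrophil chemokine, rose from 9.81 ± 1.26 to 156 ± 31.6 CPM (log2 fold change 3.98, SE 0.16, edgeR adjusted p = 1.15e-08). Plk1, a mitotic kinase, fell from 172 ± 4.12 to 56.4 ± 2.31 CPM (log2 fold change -1.61, SE 0.048, edgeR adjusted p = 2.62e-16).

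With AOA, 3750 genes were higher and 3896 lower by edgeR's test, 710 and 429 of them at least 2-fold, and 10 of 25 lists passed camera, 3 of them also with an estimated correlation. Of the 75 interferon-stimulated genes, 63 rose, 3 fell and 9 did not pass, or 66 and 4 adjusted over the list alone, and the median log2 fold change was 1.01 (camera adjusted p = 1.08e-16, or adjusted p = 0.00642 with an estimated correlation). Isg15 was at 0.75 (SE 0.070), Ccl5 at 1.85 (SE 0.067), Usp18, which removes Isg15 from proteins, at 2.18 (SE 0.15) and Ifi44 at 2.82 (SE 0.20), with edgeR adjusted p of 8.16e-09, 3.45e-15, 7.19e-11 and 1.26e-10. The members that fell, named after their values were seen, were Lgals3bp, Mov10 and Tdrd7, at -0.14, -0.39 and -0.41. Among 28 NF-kB and inflammatory targets, 25 rose, 1 fell and 2 did not pass, with a median of 1.34 (camera adjusted p = 6.48e-11, or adjusted p = 0.102 with an estimated correlation). Cxcl1, another neutrophil chemokine, rose from 153 ± 1.24 to 1232 ± 209 CPM (log2 fold change 3.01, SE 0.12, edgeR adjusted p = 6.45e-09). Lcn2, an iron-binding acute phase protein, rose from 25.05 ± 1.15 to 184 ± 7.09 CPM (log2 fold change 2.88, SE 0.059, edgeR adjusted p = 5.47e-19). The member that fell was Tnfaip2, named after its value was seen, at -0.11 (SE 0.044).

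All 24 measured G2 and M phase genes fell, also when adjusted over the list alone, with a median of -0.76 (camera adjusted p = 1.61e-13, or adjusted p = 0.00642 with an estimated correlation). Hmmr and Ttk, genes of the mitotic spindle and its checkpoint, were at -1.33 (SE 0.067) and -1.25 (SE 0.072), with edgeR adjusted p of 4.84e-13 and 5.46e-12. For 22 S phase genes, 4 rose, 10 fell and 8 did not pass, or 4 and 12 adjusted over the list alone, with camera adjusted p = 0.0680. Of 28 cholesterol and fatty acid genes, 23 fell and 5 did not pass, with a median of -0.55 (camera adjusted p = 6.48e-11, or adjusted p = 0.00394 with an estimated correlation). Mvd, of the mevalonate pathway, fell from 27.3 ± 1.48 to 6.95 ± 0.934 CPM (log2 fold change -1.98, SE 0.10, edgeR adjusted p = 3.33e-13). Scd2, a fatty acid desaturase, fell from 867 ± 29.9 to 363 ± 2.90 CPM (log2 fold change -1.26, SE 0.041, edgeR adjusted p = 8.04e-16). Of 20 endoplasmic reticulum stress genes, 2 rose and 18 fell (camera adjusted p = 1.26e-08, or adjusted p = 0.102 with an estimated correlation). Herpud1 and Syvn1, of the degradation of misfolded proteins, were at -1.66 (SE 0.061) and -1.60 (SE 0.059), with edgeR adjusted p of 1.32e-14 and 3.48e-15, while Ern1 and Atf6, stress sensors named after their values were seen, were at 0.96 and 0.34.

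Among 41 genes of ATF4 and the amino acid response, 33 rose, 4 fell and 4 did not pass (camera adjusted p = 1.00e-08, or adjusted p = 0.122 with an estimated correlation). Ddit3, the transcription factor CHOP, rose from 109 ± 3.63 to 398 ± 4.31 CPM (log2 fold change 1.87, SE 0.044, edgeR adjusted p = 4.65e-18). Ppp1r15a, a regulator of the eIF2 phosphatase, rose from 71.8 ± 5.68 to 315 ± 53.3 CPM (log2 fold change 2.13, SE 0.12, edgeR adjusted p = 1.12e-07). Slc7a11, the cystine transporter, fell from 32.1 ± 1.92 to 13.2 ± 1.90 CPM (log2 fold change -1.27, SE 0.083, edgeR adjusted p = 4.28e-11). It also belongs to the NRF2 and glutathione list of 22 measured genes, where 1 rose, 12 fell and 9 did not pass (camera adjusted p = 0.00124, or adjusted p = 0.193 with an estimated correlation). Of 14 heat shock genes, 3 rose, 10 fell and 1 did not pass (camera adjusted p = 0.00542, or adjusted p = 0.122 with an estimated correlation), with Hspa8 at -1.41 (SE 0.060). Of 20 immediate early genes, 10 rose, 3 fell and 7 did not pass (camera adjusted p = 0.0359, or adjusted p = 0.680 with an estimated correlation), with the transcription factor Myc at 1.48 (SE 0.078). The camera call of that list was lost without HT-DNA replicate 3 (adjusted p = 0.0552) and without HT-DNA+AOA replicate 2 (0.0649). Of 21 p53 targets, 11 rose, 6 fell and 4 did not pass, with camera adjusted p = 0.140, and Gadd45a, a DNA damage response gene, was at 2.13 (SE 0.12). Of 39 ribosomal protein genes, 20 rose and 19 did not pass, or 21 adjusted over the list alone (camera adjusted p = 0.000900, or adjusted p = 0.723 with an estimated correlation).

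Genes of aspartate metabolism went both ways: of 22, 10 rose, 10 fell and 2 did not pass, with camera adjusted p = 0.953. Got1 was at 0.31 (SE 0.045), Got2 at 0.17 (SE 0.042) and Asns at 0.19 (SE 0.042), with edgeR adjusted p of 4.45e-06, 0.00190 and 0.000708. Slc25a13, the mitochondrial aspartate-glutamate carrier, fell from 47.9 ± 2.21 to 27.3 ± 0.685 CPM (log2 fold change -0.81, SE 0.056, edgeR adjusted p = 9.77e-11). Of 20 components of the cGAS-STING and nucleic acid sensing list, 7 rose, 9 fell and 4 did not pass, with camera adjusted p = 0.638. Trex1 was at 1.17 (SE 0.12) and Cgas at 0.59 (SE 0.13), with edgeR adjusted p of 5.42e-08 and 0.000498. Sting1 was at -0.38 (SE 0.12) with edgeR adjusted p = 0.0132, a call that was lost without HT-DNA+AOA replicate 1 (adjusted p = 0.0555). Of 20 class I antigen presentation genes, 9 rose, 5 fell and 6 did not pass, or 10 and 5 adjusted over the list alone, with camera adjusted p = 0.190. Of 19 fibroblast and matrix genes, 5 rose, 11 fell and 3 did not pass, with camera adjusted p = 0.186. Of 34 genes of the TCA cycle and respiratory chain, 9 rose, 7 fell and 18 did not pass, or 8 and 6 adjusted over the list alone, with camera adjusted p = 0.618. Cd68 was at 249 ± 3.50 CPM under HT-DNA and 343 ± 22.1 CPM with AOA (log2 fold change 0.46, SE 0.047, edgeR adjusted p = 2.94e-08).

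The largest rises outside these lists were those of Ptprt, a receptor phosphatase, Sspo, Mamdc2 and Prr32, at 4.06 (SE 0.26), 3.71 (SE 0.24), 3.44 (SE 0.21) and 3.17 (SE 0.22). The largest falls included Vsir, an immune checkpoint receptor, at -2.03 (SE 0.19), Map1a, a microtubule-associated protein, at -1.87 (SE 0.064) and Ldb3 at -1.86 (SE 0.10). GO terms enriched among higher genes included defense response to virus (57 of 116 genes against 29.5 expected, adjusted p = 9.81e-05), and among lower genes cell division (136 of 287 genes against 81.7 expected, adjusted p = 1.59e-08), by one-sided Fisher's exact tests.

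**Figure D2:**
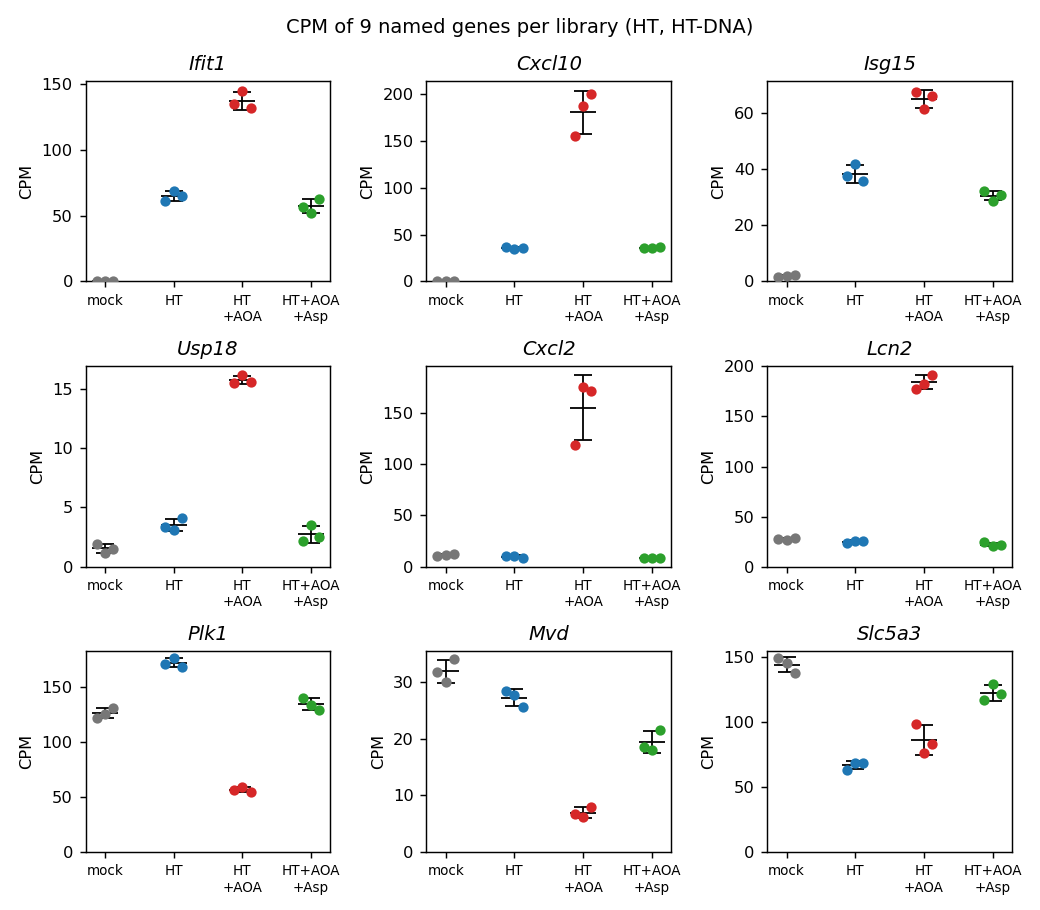
CPM of 9 named genes in each library by group (HT, HT-DNA), with a point per library and bars for the mean and SD of n = 3, on linear axes from 0. Cxcl10 averages 181 ± 22.99 CPM with HT-DNA and AOA and 35.7 ± 0.568 CPM with Asp added, and Plk1 averages 56.4 ± 2.31 and 134 ± 5.45 CPM.

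HT-DNA with AOA and Asp was compared with HT-DNA with AOA to ask whether Asp reversed what AOA had raised, a reversal that the series title names. Since no group here had HT-DNA and Asp without AOA, a reversal cannot be told apart from an effect of Asp on the HT-DNA response. Most of the genes that AOA had raised fell, and most of those it had lowered rose. Cxcl10 fell from 181 ± 22.99 to 35.7 ± 0.568 CPM (log2 fold change -2.34, SE 0.072, edgeR adjusted p = 4.04e-15). Ifit1 fell from 137 ± 6.98 to 57.2 ± 5.23 CPM (log2 fold change -1.26, SE 0.064, edgeR adjusted p = 1.13e-12). Cxcl2 fell from 156 ± 31.6 to 8.44 ± 0.166 CPM (log2 fold change -4.21, SE 0.17, edgeR adjusted p = 8.15e-09). Plk1 rose from 56.4 ± 2.31 to 134 ± 5.45 CPM (log2 fold change 1.25, SE 0.048, edgeR adjusted p = 9.19e-15).

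With Asp, 4165 genes were higher and 3874 lower by edgeR's test, 494 and 700 of them at least 2-fold, and 12 of 25 lists passed camera, 3 of them also with an estimated correlation. Of the 75 interferon-stimulated genes, 3 rose, 67 fell and 5 did not pass, with a median of -1.14 (camera adjusted p = 7.42e-19, or adjusted p = 0.0129 with an estimated correlation). The members that rose were those that AOA had lowered, Lgals3bp, Mov10 and Tdrd7, at 0.16, 0.56 and 0.29. Isg15 was at -1.08 (SE 0.071), Ccl5 at -1.94 (SE 0.068), Usp18 at -2.54 (SE 0.16), Ifi44 at -2.75 (SE 0.20) and Irgm2, an interferon-inducible GTPase, at -2.37 (SE 0.19). The edgeR adjusted p of these 5 genes was 4.12e-11, 3.61e-15, 1.33e-11, 1.73e-10 and 7.96e-10. Of 28 NF-kB and inflammatory targets, 26 fell and 2 did not pass, with a median of -1.62 (camera adjusted p = 9.97e-13, or adjusted p = 0.0717 with an estimated correlation). Cxcl1 fell from 1232 ± 209 to 104 ± 5.49 CPM (log2 fold change -3.57, SE 0.12, edgeR adjusted p = 1.88e-09). Lcn2 fell from 184 ± 7.09 to 22.1 ± 1.93 CPM (log2 fold change -3.06, SE 0.060, edgeR adjusted p = 2.45e-19).

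Among 24 G2 and M phase genes, 21 rose and 3 did not pass (camera adjusted p = 7.66e-10, or adjusted p = 0.0279 with an estimated correlation), with Hmmr at 1.15 (SE 0.067) and Cenpf, a kinetochore protein, at 1.13 (SE 0.10). Of 28 cholesterol and fatty acid genes, 18 rose, 2 fell and 8 did not pass, or 19 and 2 adjusted over the list alone (camera adjusted p = 0.000209, or adjusted p = 0.0358 with an estimated correlation), with Mvd at 1.49 (SE 0.10) and Scd2 at 1.13 (SE 0.041). Of 20 endoplasmic reticulum stress genes, 17 rose, 2 fell and 1 did not pass (camera adjusted p = 1.62e-06, or adjusted p = 0.146 with an estimated correlation), with Herpud1 at 1.82 (SE 0.061) and Syvn1 at 1.58 (SE 0.059). Of 14 heat shock genes, 11 rose and 3 fell (camera adjusted p = 0.00925, or adjusted p = 0.146 with an estimated correlation). Of 22 NRF2 and glutathione genes, 14 rose, 2 fell and 6 did not pass (camera adjusted p = 0.00586, or adjusted p = 0.268 with an estimated correlation), with Slc7a11 at 1.64 (SE 0.082). Of 14 osmotic stress genes, 10 rose, 2 fell and 2 did not pass (camera adjusted p = 0.00849, or adjusted p = 0.0717 with an estimated correlation).

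Of 41 genes of the ATF4 and amino acid response, 5 rose, 28 fell and 8 did not pass, or 6 and 29 adjusted over the list alone (camera adjusted p = 0.000209, or adjusted p = 0.309 with an estimated correlation), with Ppp1r15a at -1.61 (SE 0.11). Among 20 immediate early genes, 1 rose, 12 fell and 7 did not pass (camera adjusted p = 0.000680, or adjusted p = 0.398 with an estimated correlation), with Dusp5, a MAP kinase phosphatase, at -2.27 (SE 0.17) and Myc at -1.44 (SE 0.078). Of 39 ribosomal protein genes, 27 fell and 12 did not pass, or 28 adjusted over the list alone (camera adjusted p = 5.33e-05, or adjusted p = 0.615 with an estimated correlation), a call that was lost with length and GC trends removed (adjusted p = 0.457). Among 20 class I antigen presentation genes, 4 rose, 13 fell and 3 did not pass (camera adjusted p = 0.0401, or adjusted p = 0.513 with an estimated correlation). That call was lost without HT-DNA+AOA replicate 1 (adjusted p = 0.0637) and without HT-DNA+AOA+Asp replicate 1 (0.0516). H2-Q4, a class I gene with close copies, was at -0.90 (SE 0.054). Of 13 mitochondrially encoded messenger RNAs, 2 rose, 2 fell and 9 did not pass, with camera adjusted p = 0.952.

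Got1 was at -0.39 (SE 0.045), Got2 at -0.18 (SE 0.042) and Asns at -0.19 (SE 0.042), with edgeR adjusted p of 2.08e-07, 0.00110 and 0.000747. Cgas was at -0.67 (SE 0.13) and Sting1 at 0.40 (SE 0.12), with edgeR adjusted p of 0.000145 and 0.00842. Cd68 fell from 343 ± 22.1 to 249.8 ± 5.14 CPM (log2 fold change -0.46, SE 0.047, edgeR adjusted p = 3.36e-08). Of the 3 endothelial genes, Flt1, named after its value was seen, fell from 1.03 ± 0.277 to 0.349 ± 0.0383 CPM (log2 fold change -1.57, SE 0.43, edgeR adjusted p = 0.00404). The largest rises were those of Abcg1, a sterol exporter, at 3.38 (SE 0.24), Slco4a1 at 3.08 (SE 0.21) and Ndrg4 at 3.03 (SE 0.17), and Map1a, Ldb3 and Vsir were at 2.03 (SE 0.064), 2.11 (SE 0.10) and 1.96 (SE 0.19). Sspo, Ptprt, Prr32 and Mamdc2 were at -4.02 (SE 0.25), -3.85 (SE 0.26), -3.59 (SE 0.23) and -3.56 (SE 0.22). By one-sided Fisher's exact tests, genes that were lower with Asp were enriched for Ribosome (79 of 131 genes against 37.8 expected, adjusted p = 1.12e-11) and rRNA processing (56 of 104 genes against 27.7 expected, adjusted p = 9.94e-06), and genes that were higher for cell division (142 of 287 genes against 86.7 expected, adjusted p = 1.18e-08). Fisher's test takes genes as independent, whereas the estimated correlation within the ribosomal protein list, which lost its call as given above, was 0.673.

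Most genes called with AOA were called in the opposite direction with Asp. Of the 3750 genes higher with AOA, 2916 (77.8%) were lower with Asp, and of the 3896 lower with AOA, 3191 (81.9%) were higher with Asp. Independent lists of these sizes would share 989 and 1104 genes. Calls in the same direction numbered 30 and 20. Since both comparisons hold the HT-DNA+AOA libraries, chance values of these libraries enter both with opposite sign. Across the 14694 genes, which are not independent replicates, the fold changes had r = -0.840 and a covariance of -0.348, against a mean r of -0.520 and covariance of -0.0391 in 10 simulated data sets with no effect. On log CPM, the covariance was -0.297 with all libraries. With no HT-DNA+AOA library in both fold changes it was -0.270 on average over 6 splits (-0.280 to -0.251), so that 90.9% was left.

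Among the 2916 genes that rose and fell back, 2342 (80.3%) were not called against HT-DNA alone, 246 were still higher and 328 were lower. Among the 3191 that fell and rose back, 2537 (79.5%) were not called, 437 were higher and 217 still lower. Of all 14694 genes tested, 18.5% were called against HT-DNA alone, so both shares not called are near that of all genes. The median of the 2916 was 0.46 with AOA and -0.03 against HT-DNA alone, and that of the 3191 was -0.45 and 0.02. Of the 710 genes that rose at least 2-fold with AOA, 587 were called lower with Asp, and of the 429 that fell at least 2-fold, 364 were called higher. Of the 63 interferon-stimulated genes that rose with AOA, 62 fell with Asp, and 9 of these were then lower than under HT-DNA alone. All 25 NF-kB targets that rose with AOA fell with Asp.

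**Figure D3:**
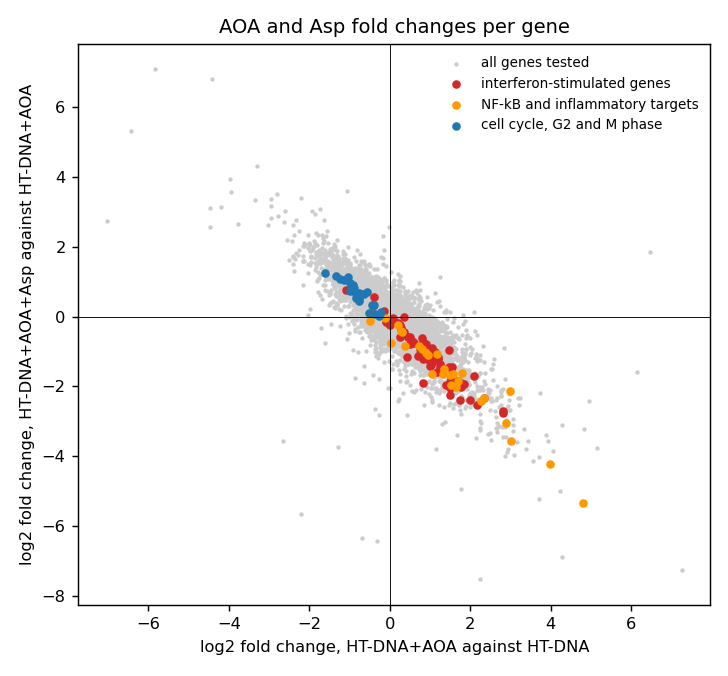
Log2 fold change of each of 14694 tested genes with AOA (x axis, HT-DNA+AOA against HT-DNA) and with Asp (y axis, HT-DNA+AOA+Asp against HT-DNA+AOA), with 3 gene lists coloured. The points follow a falling diagonal with r = -0.840, and data simulated with no effect for these libraries give r = -0.520.

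A set of 171 genes was called higher with at least a 2-fold change in HT-DNA against mock, and was therefore chosen on these data. It shares no library with the Asp comparison. With Asp, 12 of the 171 were higher, 91 lower and 68 not called, with a median of -0.77 (camera p = 2.98e-10, and p = 0.000919 with an estimated correlation). With AOA, where the shared HT-DNA libraries pull the median down, 72 were higher, 27 lower and 72 not called, with a median of 0.46 (camera p = 0.000322, and p = 0.0194 with an estimated correlation). The 30 of them in the interferon-stimulated list had medians of 1.10 with AOA and -1.30 with Asp. The other 141 had a median of 0.17 with AOA (44 higher, 27 lower; camera p = 0.115, and p = 0.240 with an estimated correlation). With Asp their median was -0.59 (camera p = 4.65e-06, and p = 0.00607 with an estimated correlation). The 234 genes lowered at least 2-fold by HT-DNA had a median of -0.0070 with AOA (48 higher, 54 lower, camera p = 0.802, and p = 0.761 with an estimated correlation). For these genes the shared HT-DNA libraries push the AOA median up. With Asp, 100 of them were higher and 21 lower, with a median of 0.45 (camera p = 9.63e-06, and p = 0.000545 with an estimated correlation).

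HT-DNA with AOA and Asp was compared with HT-DNA to ask what differed when both compounds were present. Most interferon-stimulated genes were not called, as held for most of all genes tested, of which 18.5% were called. Most sterol synthesis genes were lower, and the inositol transporter Slc5a3 was higher. Cxcl10 was at 35.6 ± 1.33 CPM under HT-DNA and 35.7 ± 0.568 CPM with both compounds (log2 fold change 0.01, SE 0.076, edgeR adjusted p = 0.964). The values for Ccl5 were 24.7 ± 1.03 and 23.3 ± 0.898 CPM (log2 fold change -0.09, SE 0.073, edgeR adjusted p = 0.444). Idi1, of the mevalonate pathway, fell from 75 ± 2.27 to 52.0 ± 1.97 CPM (log2 fold change -0.53, SE 0.053, edgeR adjusted p = 1.29e-06). Slc5a3 rose from 66.9 ± 3.06 to 123 ± 6.10 CPM (log2 fold change 0.88, SE 0.075, edgeR adjusted p = 2.17e-06).

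In this comparison 1522 genes were higher and 1197 lower by edgeR's test, 52 and 31 of them at least 2-fold, and 11 of 25 lists passed camera, 1 of them also with an estimated correlation. Without HT-DNA replicate 1 the counts were 966 and 746, without HT-DNA replicate 2 they were 952 and 737, and without HT-DNA+AOA+Asp replicate 3 they were 1002 and 726. Without HT-DNA+AOA+Asp replicate 2, 772 genes were lower. Of 75 interferon-stimulated genes, 1 rose, 10 fell and 64 did not pass, with a median of -0.14 (camera adjusted p = 0.000930, or adjusted p = 0.251 with an estimated correlation). Isg15 was at -0.33 (SE 0.073) and Apol9b at -0.42 (SE 0.066), with edgeR adjusted p of 0.00338 and 0.000183, and Ifit1 at -0.18 (SE 0.065) with edgeR adjusted p = 0.0584. Ifit1 passed under 7 of 23 alternatives, which gave adjusted p of 0.0149 to 1, among them without HT-DNA replicate 1 and without HT-DNA+AOA+Asp replicate 3. The member that was higher, named after its value was seen, was Stat2, a transcription factor of interferon signalling, at 0.36 (SE 0.061). Of 28 NF-kB and inflammatory targets, 8 fell and 20 did not pass, or 11 adjusted over the list alone (camera adjusted p = 0.000130, or adjusted p = 0.306 with an estimated correlation), with Relb at -0.59 (SE 0.087) and Cxcl1 at -0.56 (SE 0.11).

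Of 28 cholesterol and fatty acid genes, 21 fell and 7 did not pass, or 23 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 1.55e-14, or adjusted p = 0.00116 with an estimated correlation). Insig1, a brake on sterol synthesis that sterol regulators induce, was at -0.51 (SE 0.044) with edgeR adjusted p = 2.06e-07. The GO term cholesterol biosynthetic process was enriched among lower genes (14 of 22 genes against 1.90 expected, adjusted p = 6.17e-07; one-sided Fisher's exact test). Of 24 G2 and M phase genes, 10 fell and 14 did not pass, or 11 adjusted over the list alone (camera adjusted p = 8.45e-06, or adjusted p = 0.0887 with an estimated correlation), with Plk1 at -0.36 (SE 0.045) and Cdk1, the mitotic cyclin-dependent kinase, at -0.41 (SE 0.052). Of 22 S phase genes, 5 fell and 17 did not pass (camera adjusted p = 0.00236, or adjusted p = 0.251 with an estimated correlation). Of 26 nucleotide synthesis genes, 1 rose, 8 fell and 17 did not pass, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.0128, or adjusted p = 0.306 with an estimated correlation), with Rrm2 at -0.56 (SE 0.043). Of 10 core histone genes, 2 fell and 8 did not pass (camera adjusted p = 0.0497, or adjusted p = 0.306 with an estimated correlation). That camera call was lost under most alternatives, among them leaving out any of the libraries except HT-DNA replicate 3, HT-DNA+AOA replicate 3 and HT-DNA+AOA+Asp replicate 3 (adjusted p = 0.0515 to 0.332 where it was lost). Among 20 immediate early genes, 3 rose, 9 fell and 8 did not pass, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.00559, or adjusted p = 0.479 with an estimated correlation), with the transcription factor Egr1 at -1.20 (SE 0.16). Of 20 endoplasmic reticulum stress genes, 1 rose, 7 fell and 12 did not pass, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.00199, or adjusted p = 0.318 with an estimated correlation).

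Of 41 genes of the ATF4 and amino acid response, 17 rose and 24 did not pass, or 18 adjusted over the list alone (camera adjusted p = 3.36e-06, or adjusted p = 0.251 with an estimated correlation). Ddit3 rose from 109 ± 3.63 to 191 ± 8.40 CPM (log2 fold change 0.82, SE 0.044, edgeR adjusted p = 9.93e-11). Aldh1l2, of mitochondrial folate metabolism, was at 0.54 (SE 0.066). Of 14 osmotic stress genes, 6 rose, 2 fell and 6 did not pass, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00559, or adjusted p = 0.0887 with an estimated correlation), with Hspa4l at 1.06 (SE 0.060) and Slc6a9 at 0.81 (SE 0.048). The largest rises included Ppargc1a, a coactivator of mitochondrial genes, at 1.45 (SE 0.11), Abcg1 at 1.18 (SE 0.18) and the nuclear RNA Neat1 at 1.13 (SE 0.15). Among the large falls were Angptl4 at -0.88 (SE 0.071) and Phlda1 at -0.83 (SE 0.11). Prr14l at 1.28, Rbm15b at -1.07 and Rps12l1 at -1.02 were also named by the rule, with edgeR adjusted p of 0.0174, 0.0269 and 0.0308. Their calls were lost under 4, 5 and 8 alternatives, glmTreat not counted. Got1, Got2, Asns, Cgas and Sting1 were at -0.08, -0.01, 0.00, -0.08 and 0.03, with edgeR adjusted p of 0.254, 0.899, 0.981, 0.724 and 0.902.

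Of the 1197 genes lower with both compounds, 813 had been higher in HT-DNA against mock, where independent lists would share 254. Of the 1522 that were higher, 964 had been lower, where 302 would be shared. Calls in the same direction numbered 51 lower and 58 higher. These comparisons share the HT-DNA libraries. The covariance of the fold changes was -0.0802, against -0.0354 in the simulated data sets with no effect, and r was -0.446 against a simulated r of -0.489. On log CPM, the covariance was -0.0644 with all libraries. With no HT-DNA library in both fold changes it was -0.0397 on average over 6 splits (-0.0471 to -0.0308), so that 61.6% was left.

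**Figure D4:**
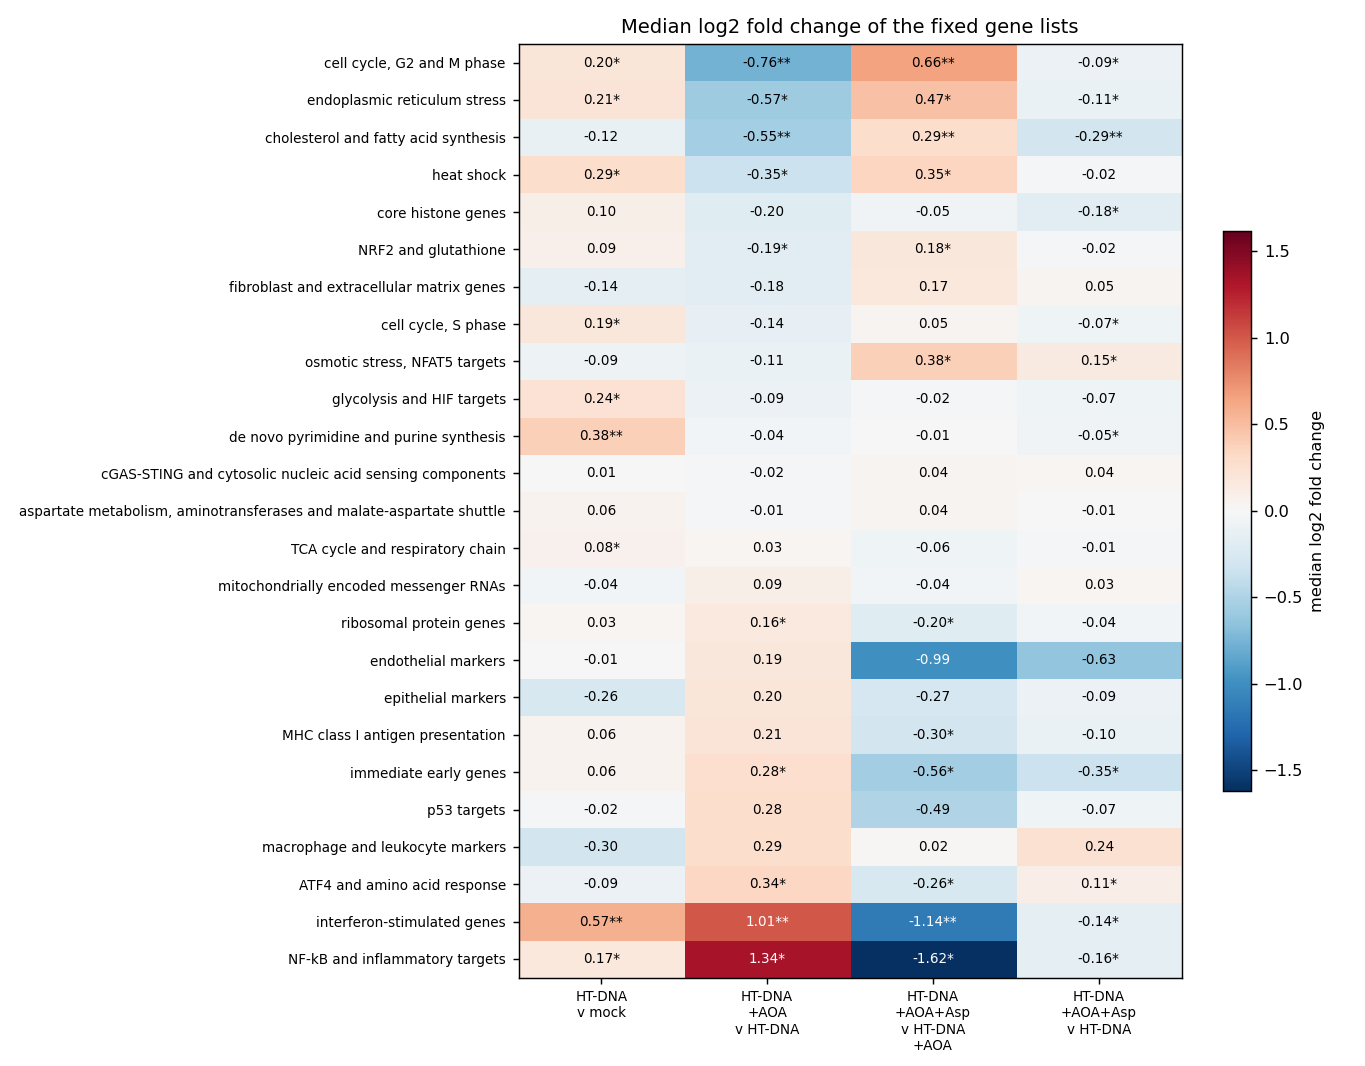
Median log2 fold change of the 25 tested gene lists (y axis) in the 4 comparisons (x axis), with colour and printed value giving the median. A single asterisk marks a camera call with the preset correlation and a second a call that also held with an estimated correlation. The interferon-stimulated list has medians of 0.57, 1.01, -1.14 and -0.14.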

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

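Removal of length and GC trends and removal of the 10 most counted genes were chosen after seeing the data, as were the alternatives for lists and the HT-DNA-induced set. All others were fixed before the data were examined. Of 230 counts of genes, 213 stayed within 1.5 times their value, and all 154 medians of the interferon-stimulated list and the HT-DNA-induced set kept their direction and side of the threshold. Of 2093 list medians, 2037 were kept, 28 lost and 25 gained a call, and 3 reversed. A change of direction between values that were both not called counted as kept. With library size alone, for example, the cGAS-STING and nucleic acid sensing list for HT-DNA went from 0.0086 to -0.054. Of 7197 fold changes of named genes, 6938 were kept by the same rule, 251 lost the call (159 of them with glmTreat), 8 gained it and none reversed. Against a fold of 1.5 with glmTreat, which asks for larger changes, the genes higher and lower were 127 and 170 for HT-DNA, 661 and 540 for AOA, 654 and 713 for Asp, and 9 and 0 for AOA with Asp against HT-DNA. In that last comparison 129 and 84 genes had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom without a fold called 1197, 1281 and 1164 lower genes. Genes that moved with AOA and back with Asp then numbered 491 and 397. Leaving out each library in turn gave 952 to 1710 higher and 726 to 1367 lower genes in AOA with Asp against HT-DNA, where fewer samples remain. The 3 reversals came with length and GC trends removed. There the mitochondrial list had medians of -0.11 with AOA (camera adjusted p = 0.0328) and 0.20 with Asp, and ribosomal protein genes 0.00697 in AOA with Asp against HT-DNA. Each passed camera there, and none had passed without that removal in the main fit. The cause was not tested. fry called 16, 19, 17 and 12 of the 25 lists for HT-DNA, AOA, Asp, and AOA with Asp against HT-DNA. Library size alone moved the split of calls from 51.7% to 39.3% higher for HT-DNA, from 49.0% to 40.3% for AOA and from 51.8% to 60.1% for Asp (4842 higher and 3209 lower, and for AOA 3116 and 4615), and the median of all genes by at most 0.062 on the log2 scale.

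With the replicate number as a block, the calls were 2974 higher and 2755 lower for HT-DNA, 3596 and 3781 for AOA, 4044 and 3737 for Asp, and 1261 and 987 for AOA with Asp against HT-DNA. Same-numbered libraries of different groups did not deviate together across all genes: over 18 pairs r was -0.151 to 0.0456, and 3 of 18 correlated best with their own number. A shared batch that affects few genes is not excluded by these correlations. Depth limits what can be said of genes at a few counts, such as the type I interferons and Ccl5 in mock.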

Other observations

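The test of interferon receptor targets, and that of the share of the HT-DNA change kept by raised genes, were chosen only after related values were seen. The other tests of this part were written before their results. The gene with the most counts in every library was Def8, at 3.80% to 5.34% of the counts. Over all libraries it held 4.67%, and the next gene, mt-Co1, 0.818%. Whether the reads counted for Def8 came from its own transcripts could not be tested from the counts. Ifit2 was at 20.9 ± 1.76 CPM in mock and 20.2 ± 3.42 CPM under HT-DNA (log2 fold change -0.05, SE 0.10, edgeR adjusted p = 0.702), while Ifit3 went from 0.807 ± 0.179 to 11.3 ± 0.439 CPM (log2 fold change 3.81, SE 0.14, edgeR adjusted p = 5.69e-15), and both were named after their values were seen. Irf7, a transcription factor that interferon induces, was at 3.77 ± 0.823 CPM in mock and 3.97 ± 0.132 CPM under HT-DNA (log2 fold change 0.07, SE 0.16, edgeR adjusted p = 0.752). With AOA it rose from 3.97 ± 0.132 to 12.8 ± 1.46 CPM (log2 fold change 1.69, SE 0.14, edgeR adjusted p = 1.85e-09), and with Asp it fell from 12.8 ± 1.46 to 3.54 ± 0.513 CPM (log2 fold change -1.85, SE 0.15, edgeR adjusted p = 5.82e-10). Irf9, a part of the complex that carries the interferon signal, was at 18.2 ± 1.05 CPM in mock and 17.8 ± 1.27 CPM under HT-DNA (log2 fold change -0.03, SE 0.078, edgeR adjusted p = 0.803). It rose from 17.8 ± 1.27 to 42.2 ± 2.69 CPM with AOA (log2 fold change 1.24, SE 0.073, edgeR adjusted p = 7.90e-12) and fell from 42.2 ± 2.69 to 15.5 ± 0.913 CPM with Asp (log2 fold change -1.44, SE 0.075, edgeR adjusted p = 1.03e-12). Eif2ak2, the kinase PKR, had log2 fold changes of -0.06 (SE 0.063), 0.45 (SE 0.062) and -0.58 (SE 0.062) in these comparisons, with edgeR adjusted p of 0.504, 2.49e-06 and 6.92e-08. These 3 genes were also chosen after their values were seen, and the differences between comparisons were not tested.

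Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. The genes called were 6023 for HT-DNA, 7646 for AOA and 8039 for Asp, with at most 0 in the other splits, and 2719 for AOA with Asp against HT-DNA, with at most 1. The absolute medians of the interferon-stimulated list were 0.57, 1.01, 1.14 and 0.14, with at most 0.27, 0.36, 0.38 and 0.09 in the other splits. For genes that moved with AOA and back with Asp, 50 splits of the 9 HT-DNA libraries were used, the real one and others drawn at random. The real split gave 6107 genes, and the highest of the others gave 50. This argues against chance only if the libraries are independent, which nothing states.

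Interferon-stimulated genes rose under HT-DNA while Ifnb1 had at most 1 count in any library. It had 1 count in HT-DNA+AOA replicates 2 and 3 and none elsewhere. Counting that leaves out single-exon genes such as Ifnb1 is argued against by 110 of 1005 named single-exon coding genes with a mean of 100 or more counts. A candidate explanation is that HT-DNA raised these genes with little signalling through the interferon receptor: 24 measured known targets of that receptor, most of them also in the interferon-stimulated list, had a median log2 fold change of 0.17 (10 higher, 1 lower, 13 not called), and with AOA 22 of the 24 were higher. The list was written after these values were seen, so the explanation stays open.

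The HT-DNA+AOA libraries stood apart from the other groups. Length and GC content as the whole cause are argued against by 92.0% of the AOA calls that stayed called with these trends removed, with an interferon-stimulated median of 0.95. Library size is argued against by totals of 20876925 to 27309291 counts, which overlap those of HT-DNA, 19944571 to 26404043. With all libraries thinned to 19944571 counts, 95% of the AOA calls stayed called, but so mild a thinning could hardly have removed many. HT-DNA+AOA+Asp also received AOA and lay at -13.4 to -12.5 on the first principal component, against 49.6 to 55.8. The biological explanation that the design gives, AOA without added Asp, stays a hypothesis. Nothing states that the replicates were separate cultures, so another difference in handling between the groups is not excluded.

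HT-DNA+AOA+Asp differed from HT-DNA against the direction of the HT-DNA change. The shared HT-DNA libraries as the whole cause are argued against by a mean covariance on log CPM of -0.0397 with none of them in both fold changes, 61.6% of the value with all libraries, and -0.0308 at the highest of 6 splits. Less HT-DNA reaching the cells of that group could lower all HT-DNA changes alike, which leaves out the cholesterol and fatty acid list (median -0.12 under HT-DNA, camera adjusted p = 0.0665, and a further -0.29 with both compounds) and Cxcl10, a single gene at 0.01. The median share of the HT-DNA change that was kept was 84.7% (95% bootstrap interval 74.6% to 89.3%) for 30 interferon-stimulated genes and 70.2% (66.2% to 74.3%) for 375 other genes, a difference of 14.5 points, with 58.6% (53.6% to 69.1%) for the 141 of these that HT-DNA raised and 74.5% (70.2% to 76.8%) for the 234 it lowered. These bootstrap intervals resample genes as if they were independent and hold no spread between libraries. Among raised genes chosen without the HT-DNA library that the share was measured on, the difference varied by library. It was 25.05, 18.4 and 9.57 points for HT-DNA replicates 1, 2 and 3, with intervals that overlap for replicate 3 alone. For the genes that moved back, less HT-DNA reaching the cells and an action of AOA with Asp therefore cannot be told apart.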
